A study of Mus with 438 samples.

How the data were processed

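The data were single-cell RNA values of mouse cones and rods, a list of ChAP-seq regions of the biotin-tagged receptor in E18 retina and a pair of ATAC-seq region lists of purified P30 cones. Per the labels, each RNA library came from 1 cell, made with SMART-Seq v4 cDNA and ThruPLEX libraries. According to the submitters' processing notes, reads were handled with bcl2fastq 2 and STAR 2.7.3a on GRCm38/mm10, and regions were called with MACS2 2.2.7.1. The counting tool, the gene annotation and the rule by which genes were kept are not given in the sources used here. Whether regions were called per sample or pooled, and how induced and suppressed regions were decided, are not given either, so the names of the lists were taken as they stand.

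The RNA table was deposited in CPM (scaled to the reads of the whole library, as made by the authors), with 10390 genes and 430 libraries. Each library's values summed to 80.0% to 93.0% of the reads that CPM counts, so other genes were left out by the authors after scaling, and each gene kept reached at least 34.4 CPM in some library. All values above 0 (100%) were whole multiples of the library's step within a tolerance of 0.1 reads, and whole reads were recovered from them. Depth per library was 8.98e+05 to 3.26e+07 reads, and the fewest genes above 0 in a cell was 2680. The ChAP list was deposited by the authors with a p-value column, from 2.67e-36 to 0.05, without a statement of whether it is a p, q or FDR value. It was used to rank regions only. Region positions in the deposited lists count from 0 at the start, and the text gives them counted from 1. RefSeq gene intervals of GRCm38.p6 gave gene positions, with 10149 genes matched by gene ID, 241 not matched and 10143 placed on chromosomes. In all, 49943 RefSeq genes were used. For 13 genes the symbol had been turned into a number by a spreadsheet, and the gene ID was used.

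Library 03 and library 14 of P60 superior control cones had a Pearson r of 0.996 across genes, where the highest pair elsewhere had 0.467. Their reads differed by a chi-square per degree of freedom of 1.91 over 3633 genes, against at least 156 for neighbouring pairs. They were taken as 1 cell sequenced again and counted once, a choice made after the data were seen, which leaves 429 cells (400 cones and 29 rods). No cell was removed for low gene number (0 cells had under 2000 genes).

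A group was the cells of 1 age, zone and genotype, and its value was the mean CPM over cells. Tests that treat cells as replicates were not used, since the labels name no animal, and the intervals over cells are those of the opsin class shares. The superior and inferior groups of the 5 control collections gave 10 values. On log2(mean CPM + 1), genes with a mean of at least 5 CPM were tested with limma 3.58.1 (trend, empirical Bayes, collection as a block) in R 4.3.3, with Benjamini-Hochberg adjustment over 10136 genes and a threshold of 0.05. The direction was superior minus inferior. Lists with at least 5 measured genes were tested with camera (preset correlation 0.01), adjusted over the 12 lists tested. The change of the zone difference with age was tested with limma on the 5 differences.

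Comparisons with 1 collection per side (knockout, P2, rods) had no test. A gene met the size rule where log2 ratios of (mean CPM + 1) were at least 2-fold in both zones in the same direction (4-fold for P2 and for rods), with a mean of at least 10 CPM and over 1 CPM in at least 25% of cells in the higher group. P60 against 2m controls was the yardstick. Medians of lists were placed among 10000 random lists of the same size matched on mean expression in 20 bins (seed 11). The same random draws were used for genes near regions, within 50 kb of the gene's interval. The plan had named the transcription start, but strand was not given in the sources used here, so this choice was made after the files were seen. Region lists were compared with Fisher's exact test on overlaps of at least 1 bp. Opsin classes used the share Opn1mw/(Opn1mw + Opn1sw) with limits of 0.9 and 0.1, and cells with under 10 CPM of both together were not classed. Intervals are exact Clopper-Pearson at 95%. The limit for a count of 0 is 3 cells of the total. Reads had no molecular identifiers, so intervals and limits cover counting error only.

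The 21 gene lists covered cone phototransduction, rod genes, photoreceptor transcription factors, dorsal and ventral retina patterning, the thyroid hormone pathway, the synaptic terminal, outer segment and cilium, glycolysis, mitochondrial respiration, immature neurons, the cell cycle, stress and immediate early genes, and markers of Müller glia, bipolar, amacrine, horizontal and ganglion cells, pigment epithelium, microglia, and endothelium and blood. Lists, tests, settings and the rule for named genes were fixed before the data were examined. The rule names Opn1mw, Opn1sw, Thrb and each list member that passes the rule of its comparison. It adds the 12 genes in each direction with the largest difference that passed the zone test in the same direction in 5 collections, the 12 in each direction with the largest smaller knockout ratio among genes past the size rule against both adult controls, the 12 in each direction for P2 and the 8 for rods. It also takes the regions within 50 kb of a named gene and the 5 ChAP regions with the smallest p-value column. As 0 genes passed the zone test, the zone genes named besides these were chosen after their values were seen.

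Alternatives were other pseudocounts (0.1 and 5), filters (none, or 20 CPM), averaging log2(CPM + 1) or taking the median over cells, no block, each collection left out, the knockout as a further pair, TMM factors, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on recovered reads summed per group, an estimated correlation or fry for lists, P60 in place of 2m controls, no detection minimum, other opsin limits, and other distances and overlaps. A further alternative and some genes are not reported here. TMM moved the median zone difference of all genes from 0.10 to 0.02. A search for thyroid hormone response elements was not run, as no genome sequence was used here.

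Procedures were tested on simulated data with known changes, made from permuted or split cells for the zone test and the size rule. The zone test recovered 4 of 49 genes changed 2-fold, 25 of 50 changed 4-fold, 29 of 50 changed 8-fold and 36 of 50 changed 16-fold, with 0 unchanged genes called. With averaged logs it recovered 2, 5, 18 and 20. The size rule recovered 25 of 50 genes changed 2.5-fold and 43 of 50 changed 4-fold, and 188 unchanged genes met it between random parts of the 2m control cells. Matched lists were tested on random values drawn independently for each gene, so genes that vary together were not covered. Of these lists, 1 of 50 unchanged lay outside the central 95% and 50 of 50 shifted lists did. Interval overlaps and gaps were right in 200 of 200 cases. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.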

Results

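The RNA of single cone photoreceptors was sequenced in cells picked from the superior or the inferior retina of mice that carry a Cre driver at the thyroid hormone receptor gene Thrb and a green reporter. Control cones (heterozygous for the driver) came from postnatal day 2 (P2; 26 superior and 30 inferior cells), P8 (24 and 24), P21 (24 and 24), P60 (26 and 21) and from a collection labelled 2 months (2m; 53 and 50). Receptor-knockout cones came from the 2m age alone (50 superior and 48 inferior), and 29 rods of the 2m age came from an Nrl reporter line. The labels also name 2 receptor-tagged and 2 control retina samples at embryonic day 18 (E18) for ChAP-seq, which pulls down the tagged receptor with its DNA, and 2 control and 2 knockout samples of purified P30 cones for ATAC-seq, which reads open chromatin. For these, 3 lists of regions were held, without values per sample.

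Each cell had between 8.98e+05 and 3.26e+07 reads. The median number of reads per cell lay between 1.74e+06 (P21 superior) and 3.25e+06 (P2 superior) in the control collections from P2 to P60. It was 1.26e+07 (superior) and 1.36e+07 (inferior) in 2m controls, 1.21e+07 and 1.09e+07 in the knockout, and 1.83e+07 in rods, so the 2m collections were the deeper batch. The median number of genes above 0 per cell ran from 3742.5 (P21 inferior) to 5824 (2m control superior). The labels name no animal, and cells of a group share animals in an unknown way. Each group of cells was therefore taken as 1 sample, and no test or error was computed from cells, except that shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error only.

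The first question was how the opsins, the light-sensing proteins that define M and S cones, are spread over the retina with age and without the receptor. S opsin (Opn1sw, gene ID 12057) was the opsin of P2 cones in both zones, at a mean of 4075 CPM in superior and 5261 CPM in inferior cells. M opsin (Opn1mw, gene ID 14539) was at 0 in each of the 26 superior cells of P2. It stood at 796 CPM superior and 521 CPM inferior at P8, and at 11413 and 2293 CPM at P21. At P60 it stood at 10221 and 2729 CPM, and in 2m controls at 9599 and 3414 CPM. S opsin was at 81034 CPM in inferior against 6456 CPM in superior cones at P21, at 72134 against 8870 CPM at P60 and at 54032 against 12658 CPM in 2m controls. In knockout cones M opsin was at 6.63 CPM superior and 1.47 CPM inferior, and S opsin at 71654 and 73742 CPM, so that S opsin stood at a like level in the superior and inferior cones of the knockout. Rods, measured the same way, held 18.4 CPM of S opsin and 0.00918 CPM of M opsin.

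Cells were classed by the M share of their opsin RNA, as M above 0.9, S below 0.1 and mixed between. All 26 superior and 30 inferior P2 cones were S cells. At P8, 19 of 24 superior cones (79.2%, 57.9 to 92.9) and 22 of 24 inferior cones (91.7%) were S. At P21, 14 of 24 superior cones were M (58.3%, 36.6 to 77.9) and the others mixed, while 23 of 24 inferior cones (95.8%) were S. At P60, 14 of 26 superior cones were M (53.8%, 33.4 to 73.4), and each of the 21 inferior cones was S. In 2m controls 12 of 53 superior cones were M (22.6%, 12.3 to 36.2), 40 were mixed (75.5%) and 1 was S, and 38 of 50 inferior cones were S (76.0%). All 50 superior and 48 inferior knockout cones were S, and a count of 0 allows up to 6.00% and 6.25% of M cells. Class shares depended on the limits where many cells lay near them: 11 of the P8 superior and 7 of the P60 superior cones were within 0.05 of a limit. With limits of 0.95 and 0.05, M cells were 30.8% of P60 and 13.2% of 2m control superior cones, and S cells 45.8% of P8 superior cones.

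**Figure D1:**
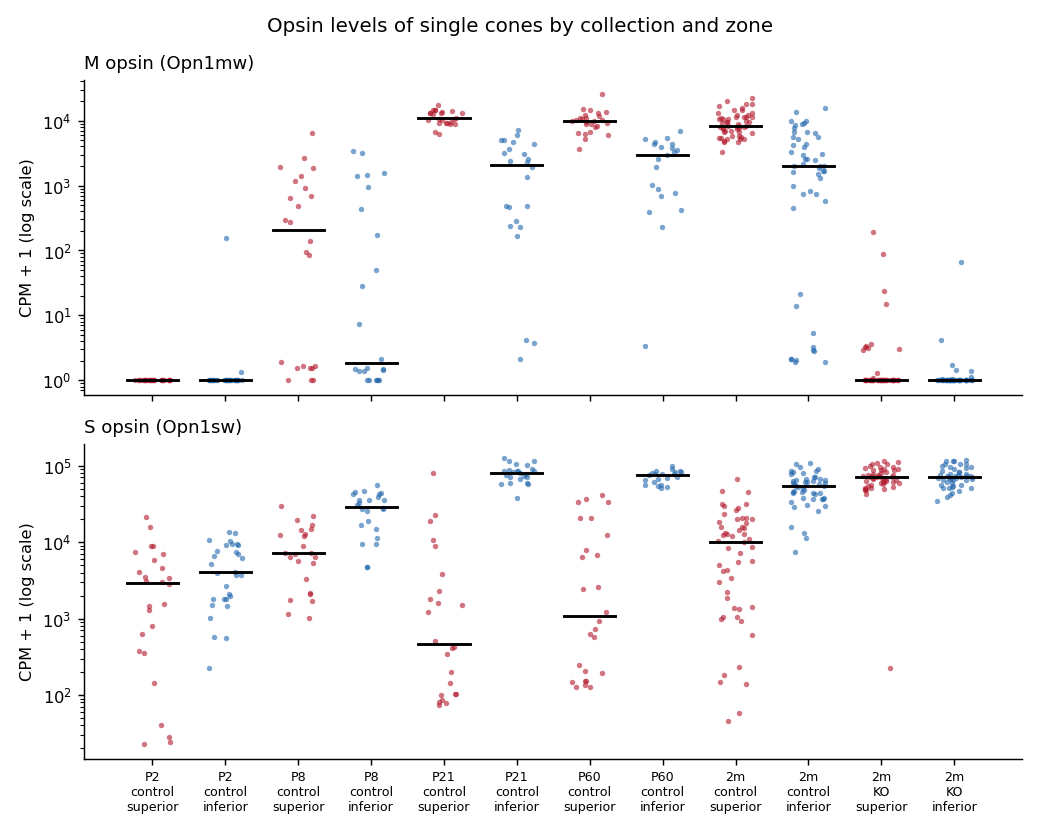
M opsin (top) and S opsin (bottom) in each cone, as CPM + 1 on a log scale, by collection and zone; each point is 1 cell and each bar the median of its group. Knockout cones of both zones had mean S opsin of 71654 and 73742 CPM, beside 72134 CPM in inferior controls of P60 and 54032 CPM in those of 2m, and mean M opsin of 6.63 and 1.47 CPM.

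The second question was which genes differ between superior and inferior control cones whatever the age. The 3 genes named by the design were S opsin, lower in superior cones in 5 of 5 collections, M opsin, higher in 4 of 5, and Thrb (gene ID 21834), the receptor gene itself, higher in 5 of 5. The mean superior minus inferior difference of log2(mean CPM + 1) was -2.15 for Opn1sw (SE 0.39), 0.74 for Opn1mw (SE 0.60) and 0.54 for Thrb (SE 0.20). Thrb differed by 0.06 at P2 and 0.08 at P8, and by 1.33 at P21, 0.89 at P60 and 0.33 in 2m controls. The Opn1mw value at P2, -2.61, rested on 1 inferior cell at 153 CPM, and without P2 the mean difference of Opn1mw was 1.58 (limma adjusted p = 0.161). None of the 3 passed the test over all genes (limma adjusted p = 0.476, 0.833 and 0.702). Averaging log values over cells, Opn1sw (adjusted p = 3.51e-04) and Opn1mw (adjusted p = 0.0124) passed and Thrb did not (adjusted p = 0.419), and with DESeq2 Opn1sw passed (adjusted p = 0.0412). In an exact sign-flip test over the 5 collections, two-sided, p was 0.0625 for Opn1sw, 0.0625 for Thrb and 0.5 for Opn1mw, and 0.0625 is the smallest p that 5 pairs can give.

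Across all 10136 genes tested, limma with the collection as a block called 0 genes at an adjusted p below 0.05, with 710 genes at an unadjusted p below 0.05. The smallest adjusted p was 0.275, for Vax2, a homeodomain factor of the ventral retina. Averaging log values over cells instead of CPM gave 10 genes higher in superior and 6 higher in inferior cones (847 at p below 0.05). DESeq2 on recovered reads gave 127 and 109 (1291 at p below 0.05), and edgeR gave 0 (413 at p below 0.05). Without the deeper 2m collection, limma called 0 genes (568 at p below 0.05).

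The averaged-log list held Opn1mw, Opn1sw and 14 other genes, which were named after their values were seen, as was En2, which is not on it. Their values are those of the limma test above. In the inferior direction, Vax2 had a mean of 59.6 CPM in inferior and 0.0214 CPM in superior cones, and the transcript Vax2os beside it 14.6 and 0.0126 CPM. En2, a homeodomain factor, had 27.4 CPM in inferior and 0.0177 CPM in superior cones, and Syndig1l, of a family of synapse-inducing membrane proteins, 319 and 57.3 CPM. Kcne2, a potassium channel subunit, differed by -1.40 (log2) and Ccdc136, the neighbour of Opn1sw, by -1.09. In the superior direction, Samd7, a transcriptional repressor of photoreceptors, differed by 3.59 (SE 0.59), the DNA repair enzyme Smug1 by 3.43 (SE 0.50) and the Rab-regulating gene Tbc1d2 by 3.37 (SE 0.77). Stom, Desi1, Ptp4a2, Kpna2 and Pja1 differed by 1.35, 1.17, 1.06, 1.04 and 0.91, and A930001M01Rik by 2.35. Each held its direction in 5 of 5 collections, except En2 and Kpna2, in 4 of 5.

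**Figure D2:**
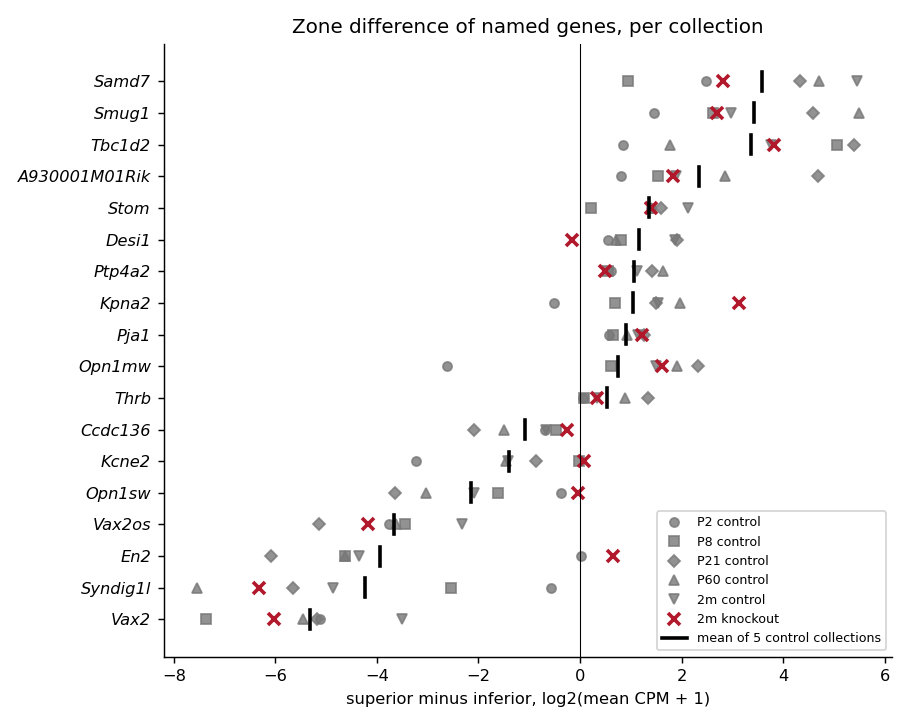
Superior minus inferior difference of log2(mean CPM + 1) for named genes (x axis), with a grey symbol per control collection, a red cross for the knockout and a black bar for the mean of the 5 control collections. The knockout value lies near 0 for Opn1sw (-0.04) and at -6.02 for Vax2.

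Among the 12 gene lists tested in this comparison, the rod gene list and the cone phototransduction list were lower in superior cones. Of 16 rod genes measured, Sag, Reep6 and Pde6b were lower (-0.39, -1.05 and -3.00) and Samd7 higher when adjusted over the list alone, where 0 passed over all genes, and the list had a median of -0.44 (camera adjusted p = 2.53e-04). That call was lost with an estimated correlation (adjusted p = 0.568 with an estimated correlation). RNA of rods in the picked cells was not excluded as its source. Of 19 cone phototransduction genes, Opn1sw, the transducin subunit Gnb3 (-0.25) and the cyclase activators Guca1a (-0.44) and Guca1b (-1.25) were lower when adjusted over the list alone, again with 0 over all genes, and the list median was -0.11 (adjusted p = 0.00561, and adjusted p = 0.274 with an estimated correlation). Without P2 the adjusted p of that list was 0.191.

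The other 10 lists did not pass, and 0 of their genes passed when adjusted over the list alone. Their adjusted p was 0.0936 for glycolysis, 0.138 for mitochondrial respiration, 0.172 for immature neuron genes, 0.188 for synaptic terminal genes and 0.761 for photoreceptor transcription factors and for outer segment genes. It was 0.901 for the thyroid hormone pathway and for stress genes, and 0.918 for cell cycle genes and Müller glia markers. Without the 2m collection, glycolysis (adjusted p = 0.005) and mitochondrial respiration (adjusted p = 0.00827) were higher in superior cones, but with an estimated correlation both were lost (adjusted p = 0.508 each). The sign of the median was opposite to the direction of the test for the outer segment (0.02, tested lower), cell cycle (0.12, lower), stress (0.08, lower), Müller glia (0.10, lower) and transcription factor (-0.01, higher) lists. The dorsal and ventral patterning lists had too few measured genes for a list test. The 3 dorsal genes Efnb1, Aldh1a1 and Nr2f2 summed to a mean of 47.99 CPM in superior and 0.542 CPM in inferior 2m controls, and the ventral pair Vax2 and Ephb2 to 1.22 and 13.9 CPM.

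Whether the zone difference changes with age was tested on the 5 differences, P2, P8 and P21 against P60 and 2m. Limma called 0 genes (507 at p below 0.05, smallest adjusted p 0.729), and no other tool was run for it. The zone differences of Opn1sw (-3.65) and Thrb (1.33) were largest at P21. Grouping P21 with P2 and P8 could therefore hide a change between P8 and P21, and recovery of known changes by this test was not simulated. In the knockout the zone difference can be given but not tested, as it has 1 superior and 1 inferior group. S opsin differed by -0.04 in knockout against -2.09 in 2m control cones, and En2 by 0.64 against -4.35. Differences of Vax2 (-6.02 in knockout), Syndig1l (-6.33), Samd7 (2.82), Smug1 (2.71) and Tbc1d2 (3.81) had the direction of the controls.

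The third question was what differs in adult cones without the receptor. Thrb RNA itself was at 43.2 CPM in superior and 33.9 CPM in inferior knockout cones, against 213 and 170 CPM in 2m controls and 358 and 192 CPM at P60. It was at 897 and 861 CPM at P2, 273 and 259 CPM at P8, 443 and 176 CPM at P21, and 67.3 CPM in rods. The mean of rods rested on few cells: 3 of 29 were over 1 CPM, with a maximum of 1796 CPM and a median of 0.087 CPM. Values cover the whole gene, so the deleted part was not checked. In total 21 genes were higher and 58 lower by at least 2-fold in both zones against both adult control collections, which is called the size rule here and is a description, not a test. M opsin was the lowest, with a log2 ratio of -10.30 superior and -10.43 inferior against 2m controls.

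Several genes that control cones of both zones expressed were close to absent from the knockout. Rd3l, a relative of the photoreceptor gene Rd3, had 299 and 338 CPM in 2m control superior and inferior cones and 0.0120 and 1.97 CPM in knockout cones. Glb1l2, a galactosidase-like gene, had 137 and 119 CPM against 0.0249 and 0.00207 CPM. The synaptic pentraxin Nptx2 had 62.6 and 26.6 CPM against 0.0273 and 0 CPM, and the protease gene Pgc 14.6 and 25.6 CPM against 0 in both zones. Fzd10, a Wnt receptor, Gabrr3, a GABA receptor subunit, Lynx1, a modulator of nicotinic receptors, and the homeodomain-only gene Hopx had log2 ratios of -5.81, -4.46, -3.94 and -3.27 in superior and -2.83, -3.47, -4.04 and -2.69 in inferior cones. Agr2, Lrtm1 and Gm4827 completed the 12 lowest genes. Members of the fixed lists that were lower against both controls included, besides Opn1mw and Thrb, cone arrestin Arr3 (-1.07 and -1.62), Samd7 (-4.59 and -1.94), the hormone-responsive factor Klf9 (-1.81 and -1.30), and the glycolytic enzymes Aldoc (-1.21 and -1.56) and Ldhb (-2.60 and -3.09).

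Among the genes higher in knockout cones, the presynaptic adhesion gene Nrxn3 had 220 and 186 CPM in superior and inferior knockout cones against 18.8 and 30.3 CPM in 2m controls. Tmem158 had 194 and 66.8 CPM against 16.4 and 15.8 CPM, and Mfng, a glycosyltransferase that acts on Notch, 59.7 and 84.6 CPM against 12.5 and 19 CPM. Apobec2, Gm10419, A930009A15Rik, 9430037G07Rik, Abhd14b, N4bp2l2 and Zfp783 were others named, and Apoe (1.12 and 1.44) was the list member that was higher. Xist, the RNA made from the inactive X chromosome of female cells, had 177 and 142 CPM against 8.61 and 19.1 CPM in 2m controls and 0 in both zones of P60. It exceeded 1 CPM in 36 of 50 and 27 of 48 knockout cells, in 15 of 53 and 18 of 50 cells of the 2m controls and in 0 of 26 and 0 of 21 cells of P60, so the collections differed in it whatever the genotype. The size rule took no account of the sex of the animals, which may differ between collections.

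The yardstick for these counts is the difference between the control collections. Sampling of cells adds to such counts: 188 unchanged genes met the 2-fold rule between random parts of the 2m control cells, which hold fewer cells than the whole groups. Against 2m controls alone, 128 genes were higher and 127 lower in knockout cones (62 and 280 when log values were averaged over cells), and against P60 controls alone 219 and 258, while P60 against 2m controls, of one genotype, gave 334 and 315. By the same rule against both other adult collections, the 2m controls had 34 genes higher and 43 lower, and the P60 controls 79 and 167. This order depended on how cells were averaged. With averaged logs the knockout had 16 genes higher and 106 lower, the 2m controls 86 and 20 and the P60 controls 255 and 65, and 49 of the 79 knockout genes were kept. Superior and inferior ratios of knockout over 2m control had a Pearson r of 0.174 across genes, which are not independent replicates.

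**Figure D3:**
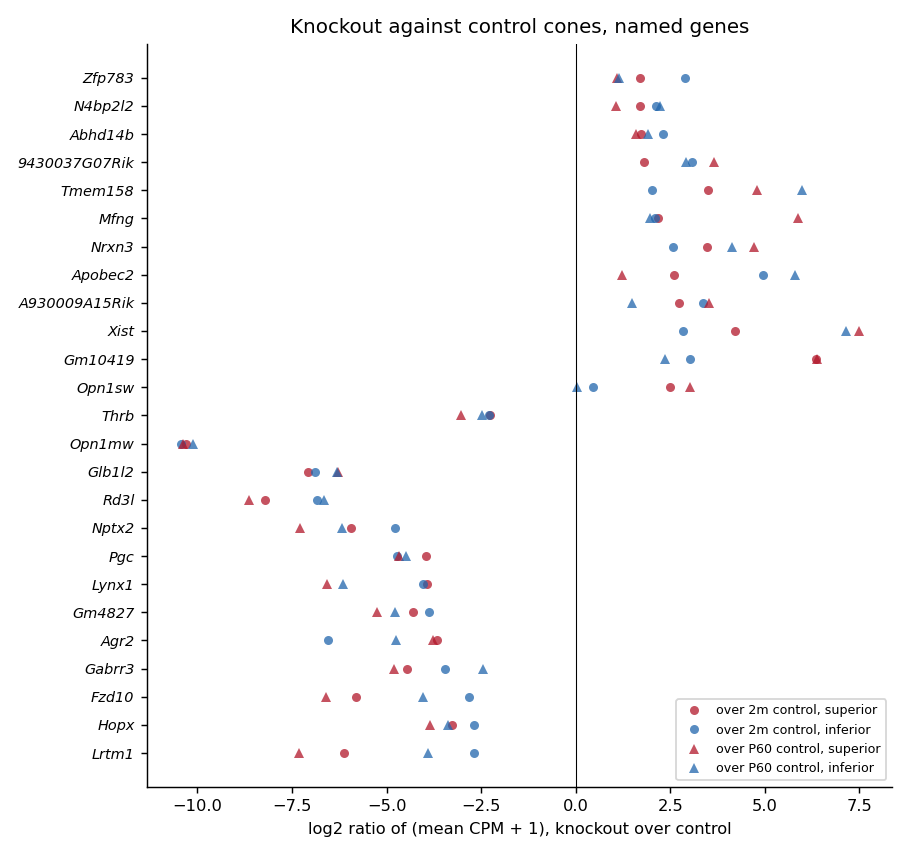
Log2 ratio of (mean CPM + 1), knockout over control, for named genes (x axis), against 2m (circles) and P60 (triangles) controls, superior in red and inferior in blue. Opn1mw lies between -10.43 and -10.11 in the 4 ratios; where a group is at 0, as Pgc in knockout or Xist at P60, the ratio depends on the added 1.

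Of the fixed lists, 5 lay outside the central 95% of 10000 random lists matched on expression, against 2m controls. Müller glia markers were lower, with a median log2 ratio of -2.45 (percentile 0), 1 of 8 measured members meeting the size rule downward (Rlbp1) and 1 upward (Apoe). Glycolysis genes were lower, with a median of -0.47 (percentile 0.07), with Pfkm, Pfkp, Aldoc and Ldhb of 17 lower and Gapdh higher. Stress and immediate early genes were higher, at 0.73 (percentile 99.3), with Hspa1b and Ddit3 of 9. The synaptic terminal list (0.19, percentile 99.1) and the outer segment list (0.19, percentile 99.5) had 0 of 24 members each past the size rule. Against P60 controls these medians were -0.27, 0.07, -0.46, -0.33 and -0.20 in that order, so 4 of the 5 had the opposite sign. P60 over 2m controls gave -1.61, -0.64, 1.51, 0.43 and 0.31, in the direction of the knockout difference.

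The other 7 lists lay inside the central 95%. Their medians were 0.07 for cone phototransduction (percentile 90.3), where Guca1b of 19 genes was higher and Opn1mw and Arr3 lower, and -0.29 for rod genes (percentile 6.6), where Slc24a1 and Reep6 of 16 were higher and Gnat1, Pde6b and Samd7 lower. They were 0.05 for photoreceptor transcription factors (percentile 66.0), with Otx2 higher, and -0.08 for the thyroid hormone pathway (percentile 26.7). Mitochondrial respiration (-0.16, percentile 22.5), immature neuron (0.18, percentile 74.4) and cell cycle genes (-0.11, percentile 30.4) had 0 members past the size rule. The mean of the cone phototransduction list was -0.33, opposite in sign to its median.

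The fourth question was how P2 cones differ from adult cones. Genes of immature neurons stood out at P2: Sox4, a factor of differentiating neurons, was at 310 CPM in superior and 259 CPM in inferior cones and at 0 at P60, and Stmn1, a microtubule regulator, at 1299 and 1295 CPM against 11.6 and 4.63 CPM at P60. Cone arrestin Arr3 stood at 45 and 74.5 CPM at P2 and at 7406 and 5717 CPM at P60. The matrix gene Impg1 and the orphan receptor gene Gpr152 were at 0 at P2 and at 490 and 180 CPM and 247 and 261 CPM at P60. By at least 4-fold in both zones against both adult collections, 191 genes were higher and 158 lower at P2. Among the highest were also Nck2, Mtnr1a, Gldc, Marcksl1, Kcnd3, Cdh13, Lhx2, Serinc5, Tagln2 and Nt5dc2, and among the lowest Opn1mw, Cds1, Pdzph1, Car8, Cacnb2, Ccl9, Drd4, Lrtm1 and Gnat1.

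By list, 7 of 13 immature neuron genes were higher at P2 (median log2 ratio 3.31, percentile 100), among them Insm1, Hes6 and Tubb2b, and 4 of 18 photoreceptor transcription factors (1.69, percentile 100), namely Otx2, Onecut1, Prdm1 and Isl2. Lower lists were cone phototransduction (-2.47, percentile 0, 9 of 19 genes, such as Gnat2, Pde6c and Pde6h), rod genes (-2.51, percentile 0; Gnat1, Gngt1, Sag and Rom1), synaptic terminal genes (-1.12, percentile 0; Cplx4, Slc17a7, Cacnb2 and Cabp4), outer segment genes (-0.73, percentile 0.01; 6 of 24, such as Prph2 and Abca4) and glycolysis genes (-1.22, percentile 0.02; Hk1, Hk2 and Aldoc). The thyroid hormone pathway (1.31, percentile 99.8) had 1 of 14 members past the rule, Dbp, which was lower. Cell cycle genes (4.25, percentile 100) had Ccna2 of 5. Their median was 1.19 (percentile 96.47) with averaged logs, inside the random range and with 0 members past the rule. The mitochondrial (-0.21, percentile 5.76) and stress lists (0.30, percentile 38.7) lay inside the random range with 0 members. Markers of other cells moved with these groups: Müller glia markers had a median of 2.31 (percentile 99.98). Of these, Apoe, Dkk3 and Vim were higher and Clu lower. Averaging logs over cells put the Müller glia median at 1.15 (percentile 96.42), inside the random range, with 1 member higher and 1 lower. Pax6 of the amacrine and Kdr of the endothelial list were also higher at P2. The rod gene median was -1.03 with averaged logs, still at percentile 0. P2 was 1 collection, so its age and its batch cannot be told apart.

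Rods gave the contrast of cell types. The rod transducin gene Gnat1 had a log2 ratio of rods over 2m control cones of 8.07 superior and 6.92 inferior, and Gnb1, Nr2e3, Slc24a1, Gpsm2, Kcnj14 and Cngb1 were next among the highest. The cone transducin gene Gnat2 had a log2 ratio of -12.73 and -12.77, followed by Ramp2, Arr3, Opn1mw, Pde6c, Pde6h, Cngb3 and Opn1sw. By at least 4-fold in both zones, 62 genes were higher and 1166 lower in rods. Of 16 measured rod genes 11 were higher, and of 19 cone phototransduction genes 11 were lower and 1 higher (Guca1b). Müller glia markers moved with the rods: Rlbp1, Glul, Apoe and Dkk3 of 8 were higher. Other members past the rule included Rorb, Prph2, Fscn2 and Hspa1b, which were higher, and Rxrg, Prdm1, Six6, Hr, Ncor1, Ctbp2, Cplx3, Rims2, Sv2a, Rpgr, Pcdh15, Pfkm, Eno2, Ndufs1, Ndufs3, Uqcrfs1, Btg2, Tmsb10 and Cabp5, which were lower. Of 29 rods, 28 had too little opsin RNA of either cone type to be classed.

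The fifth question was where the receptor binds and how its sites relate to chromatin and RNA in cones. The ChAP list held 4590 regions of 300 bp, the list of ATAC regions named induced by the receptor 5049 regions (median 439 bp) and the list named suppressed 4072 (median 485 bp). Of these, 69.7%, 68.5% and 60.8% lay in a RefSeq gene (build GRCm38, positions counted from 1). Of the induced regions 1292 (25.6%, 24.4 to 26.8) overlapped a ChAP region, against 105 suppressed regions (2.58%, 2.11 to 3.11). The odds ratio was 12.99 (Fisher's exact test, two-sided, p = 3.79e-239), where neighbouring regions are not independent. The regions with the smallest values of the deposited p-value column were at chromosome 11, 78787586 to 78787885 (2.67e-36, 35857 bp from Ccnq), in Pde6b at chromosome 5, 108422195 to 108422494 (2.88e-32), and at chromosome 12, 111982803 to 111983102 (3.14e-32), within Tdrd9 and 1486 bp from Rd3l. The next were in Arhgap26 and 4930471C04Rik (2.71e-29 and 3.11e-29).

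Genes lower in the knockout by the size rule lay near induced regions. Of 57 such genes with a position, 48 (84.2%, 72.1 to 92.5) had an induced region within 50 kb of the gene, against a mean of 35.99% in random genes matched on expression, and 46 (80.7%, 68.1 to 89.95) had a ChAP region, against 39.2%. Suppressed regions lay near 4 of them (7.02%, random mean 12.5%). Of 19 placed genes higher in the knockout, 9 (47.4%, 24.4 to 71.1) had a suppressed region within 50 kb, against 12.7%. Genes that set the 2m or the P60 control collection apart by the same rule had induced regions in 21.2% to 48.1% and suppressed regions in 6.49% to 22.5%. The interval of the highest suppressed share (10.8 to 38.5, genes lower in 2m controls) overlapped that of the genes higher in the knockout. Genes higher in P60 controls also exceeded random genes. Their share was 48.1% near induced regions (random mean 35.2%, percentile 98.9) and 54.55% near ChAP regions (38.1%, percentile 99.8). Genes lower in P60 controls fell below random genes (24.7% and 25.9%, percentiles 0.14 and 0.04). Genes are not independent replicates, and no p was computed across them.

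**Figure D4:**
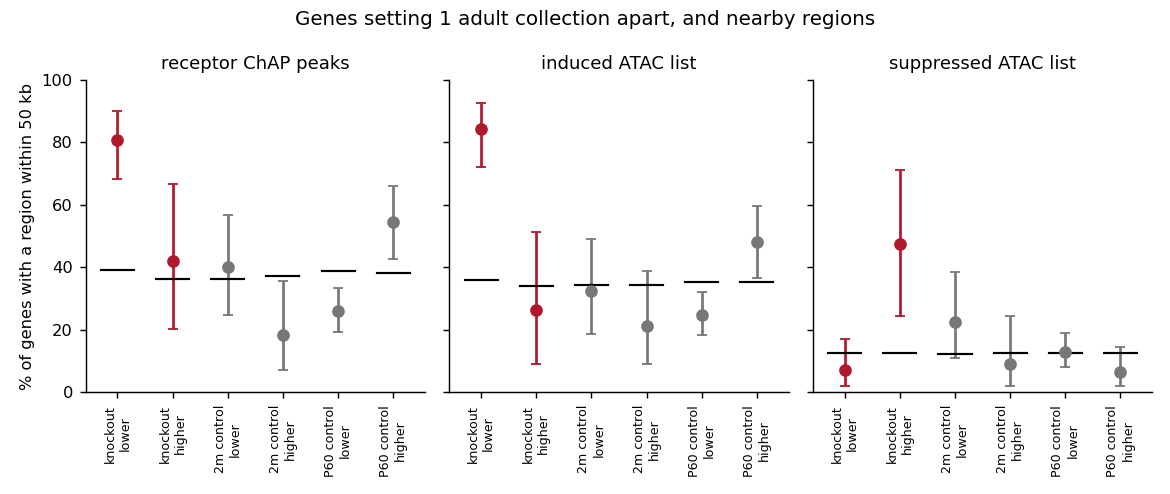
Percent of genes with a ChAP region (left), an induced region (middle) or a suppressed region (right) within 50 kb, for genes that set the knockout, the 2m control or the P60 control apart by size; whiskers are exact 95% intervals and dashes the mean of 10000 matched random lists. Genes lower in knockout reach 84.2% for induced regions, and genes higher in knockout 47.4% for suppressed regions.

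Over all genes with a region within 50 kb the shift was small and depended on the control collection and on how regions were assigned to genes. The median log2 ratio of knockout over 2m control was 0.10 for 3960 genes near ChAP regions (percentile 100 of matched random lists), 0.04 for 3600 genes near induced regions (percentile 8.10) and 0.13 for 1335 genes near suppressed regions (percentile 99.97). For induced regions it was -0.0553 within 10 kb and -0.0652 for the nearest gene of each region (percentile 0 in both). For ChAP regions it was 0.0926 within 10 kb (percentile 99.78) and 0.0583 for the nearest gene (percentile 80.8, inside the random range). For suppressed regions it was 0.20 and 0.19 (percentile 100 in both). Against P60 controls the medians were -0.08, -0.12 and 0.21, opposite in sign for ChAP and induced regions and of the same sign for suppressed regions. P60 over 2m controls gave 0.15, 0.15 and -0.06. The planned test of zone genes near ChAP regions was void with 0 zone genes. For the averaged-log list 14 of 15 placed genes had a ChAP region within 50 kb against 39.03% of the others (Fisher's exact test, p = 1.84e-05), and for DESeq2 107 of 230 (p = 0.0239), where genes are not independent replicates. Opn1sw and Ccdc136, and Vax2 and Vax2os, are neighbours that can count the same regions. These tests were not matched on expression or gene length.

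At the S opsin gene (chromosome 6, 29376671 to 29380513) 10 suppressed, 1 induced and 3 ChAP regions lay within 50 kb, and the induced region at 29365351 to 29365811 held a ChAP region. A suppressed region at 29379399 to 29380817 and a ChAP region at 29380490 to 29380789 (1.20e-19) overlapped the gene's higher end. The M opsin gene (chromosome X, 74127466 to 74150756) had 7 induced and 0 ChAP regions, with induced regions at 74127180 to 74127813, across its lower end, and at 74151676 to 74152706, 920 bp outside it. Thrb (chromosome 14, 17659225 to 18040097), which carries the driver, had 8 induced, 1 suppressed and 5 ChAP regions, and the ChAP region at 17963713 to 17964012 (9.23e-25) lay inside an induced region. Rd3l (chromosome 12, 111979191 to 111981317) had 9 induced regions and the ChAP region already given. Nptx2 and Fzd10 had 10 induced regions each, Lynx1 had 8 and Pgc had 6. Of the genes higher in knockout, Nrxn3, which spans chromosome 12 from 88722701 to 90334935 and so has more room for regions, had 24 suppressed regions and Gm10419 had 7, with 1 induced and 1 ChAP region each. En2 had 4 suppressed and 2 ChAP regions, Vax2 and Vax2os had 2 ChAP regions each, and Samd7 had 2 ChAP and 2 induced regions. Exons and introns were not analysed here.

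**Figure D5:**
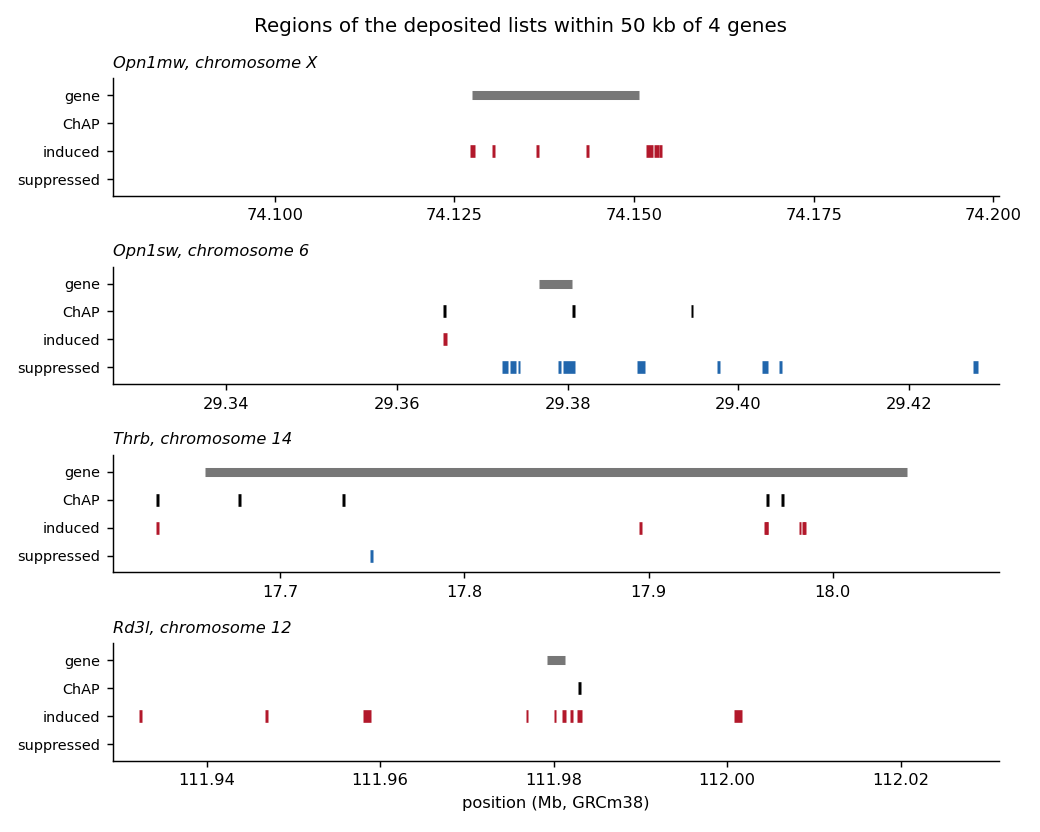
Regions of the 3 deposited lists within 50 kb of Opn1mw, Opn1sw, Thrb and Rd3l, with the gene as a grey bar, ChAP regions in black, induced regions in red and suppressed regions in blue, against the position in Mb (GRCm38). Opn1sw has 10 suppressed regions and Rd3l 9 induced regions.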

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

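The tests of Müller glia RNA, of receptor loss and of S opsin RNA from other cells were chosen after their results were seen.

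The zone difference of En2 at P2, 0.02, stood apart from -6.09 to -4.35 in the other 4 control collections, with a gap of 0.715 of the whole range against a limit of 0.71. Of 18 sets of 5 collections tested this was the 1 beyond the limit, and chance puts about 1 in 20 there. As the superior mean of En2 over the 5 collections was 0.0177 CPM, its P2 value means that its RNA was near 0 in both zones. The zone difference of Kcne2 was 0.0881 in knockout cones against -3.23 to -0.02 in the 5 control collections, and that of Desi1 was -0.153 against 0.54 to 1.91. Both are on the opposite side of 0 in the knockout, and neither difference was tested.

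For the zone test the real grouping gave 0 genes and the highest of the other splits of the 10 group values gave 30. As no split can give fewer than 0 genes, the count of splits decides nothing about chance. The 16 splits that part all 5 pairs gave 0 genes each. The 5 splits with 30 genes parted the P21 pair and no other, so with the collection as a block they compared P21 superior with P21 inferior cones alone.

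The 58 genes lower in knockout cones against both adult controls by mean CPM (106 with averaged logs) are the first pattern. The lower bound of the share near induced regions, 72.1%, lay above the highest upper bound in the other sets, 59.7%. That argues against differences between collections, whatever the genotype, as the whole source. The intervals treat genes as independent, which they are not. Genes higher in P60 controls also exceeded matched random lists (percentile 98.9), so a part from such differences stays open. Less rod RNA was argued against by a median log2 ratio of rods over cones of -3.18, with 49 of the 58 lower in rods. Less RNA of Müller glia, bipolar or amacrine cells stays open: 1.72% of the genes were on marker lists, of which few genes were measured. The Müller list was at -0.27 against P60 and -2.45 against 2m controls. Amacrine markers summed to 55.5 and 19.3 CPM in superior and inferior knockout cones. They summed to 22.5 and 13.6 CPM in 2m controls and to 45.5 and 40.3 CPM in P60 controls. The bipolar markers Cabp5 and Lhx4 were higher in the knockout than in 2m controls in both zones. Both also differed between zones in 2m control cones (-2.56 and 3.38), and Lhx4 is known from cones, so they cannot decide on bipolar RNA. Loss of the receptor, the group named by the design, may account for the pattern: the share near induced regions stood at percentile 100 of matched random lists. It stays a hypothesis, as the ATAC lists were themselves made from control and knockout cones, and with 1 knockout collection a difference of its animals other than the receptor stays open.

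The second pattern is that M cells made up 22.6% of superior cones in 2m controls (12.3 to 36.2) against 53.8% at P60 (33.4 to 73.4), with intervals that overlap and a difference that was not tested. With limits of 0.95 and 0.05 the shares were 13.2% and 30.8%. Thinning the 2m libraries to 1.94e+06 reads left the count at 12 of 53 (22.6%, 12.3 to 36.2, against a P60 lower bound of 33.4%). Redrawing reads barely moves a share between 2 abundant RNAs, so the thinning could not decide whether the number of reads was the source. Other differences between the batches were not covered by it. S opsin RNA from other cells stays open: rods of the 2m age had a median of 0.316 CPM against 9991 CPM in superior cones, but they came from another mouse line. Where along the superior retina the cells were picked, and the animals, may differ between collections and could not be tested beyond these values, and no biological explanation was tested.

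The third pattern is the zone differences shared by P21 and P60. Of 218 genes at least 2-fold apart in both that could be followed, 24.3% (18.8 to 30.6) were 2-fold apart in the same way in knockout cones, against 8.14% of other genes (7.46 to 8.86). This argues against all of these differences needing the receptor, and the share in 2m controls was 26.6% (20.9 to 32.99) against 9.11%. Which genes depend on the receptor stays open with 1 knockout collection.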

How the results depend on the processing

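An alternative of the list test and the alternative with both libraries of the repeated cell were chosen after the data were seen. Of single cells, no paired analysis was possible because the numbers in titles count cells within a group; superior and inferior groups were paired by collection in the zone test. Of 598 alternative values of 92 results, 460 kept their direction and side of the threshold or stayed within their spread and 138 did not. The cause was not tested unless stated. The number of zone genes was 0 in 14 alternatives, edgeR among them (230 to 744 genes at p below 0.05), and 16 with averaged logs, 2 without the block, 1 with the knockout as a further pair and 236 with DESeq2. For lists it was 0 with averaged logs, 0 with an estimated correlation, 0 with fry and 1 to 4 when leaving out a collection. The cone phototransduction adjusted p was 0.134, 0.274 and 0.399 with averaged logs, an estimated correlation and fry, and 0.00292 to 0.191 when leaving out a collection. For rod genes it was 0.184, 0.568 and 0.399, and 0.771 in the alternative of the list test chosen later. The test of age on the zone difference gave 0 genes in 7 of 7 alternatives. Of 320 values of named zone genes, 33 passed the threshold that limma did not reach and 0 reversed. The genes named after their values were seen, except En2, were chosen for passing with averaged logs, so their passes there were fixed beforehand.

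With averaged logs, the knockout had 62 genes higher and 280 lower than 2m controls, 106 lower than both controls, the yardstick had 504 higher and rods 33 higher. With no detection minimum, which admits more genes, these were 412 higher and 344 lower, 100 and 126 against both controls, 582 and 575 for the yardstick, and 217 higher and 2691 lower in rods. Against P60 the knockout had 219 higher and 258 lower. Counts for P2 stayed within 1.5 times in each alternative. Of 104 values of named knockout genes 48 moved and 0 reversed. These genes, except Opn1sw, had met the size rule against both adult controls, so the P60 alternative could not reverse them. Knockout list medians against P60 were -0.33 (synaptic terminal), -0.20 (outer segment), 0.0748 (glycolysis), -0.46 (stress) and -0.27 (Müller glia), and with averaged logs -0.0691 (outer segment), -0.72 (glycolysis) and -0.88 (Müller glia). With opsin limits of 0.8 and 0.2 the S share was 95.8% at P8 superior, 100% at P21 inferior, 15.4% at P60 superior and 88.0% in 2m inferior controls. With 0.95 and 0.05 it was 45.8% at P8 superior, 71.4% at P60 inferior and 0% in 2m superior controls, and the M share at P60 superior was 30.8%. Medians near regions were 0.0583 (ChAP), -0.0652 (induced) and 0.19 (suppressed) for the nearest gene, -0.0553 (induced) and 0.20 (suppressed) within 10 kb, and -0.0751, -0.12 and 0.21 against P60. The overlap of the region lists kept its direction, with odds ratios of 9.07 to 22.6. Removing cells under 2000 genes changed nothing, as there were 0, the median over cells gave no value for En2, and the response element search and the zone test near regions gave no value. The P2 to P60 collections had 8.98e+05 to 5.11e+06 reads per cell.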

Other observations

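No tests were run on the values of this part, and its genes other than the marker lists were chosen after their values were seen.

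Genes that mark the dorsal and ventral retina differed between zones in knockout cones in the same direction as in 2m control cones. Nr2f2, an orphan receptor of the dorsal retina, had 23 CPM in superior and 0.0447 CPM in inferior 2m controls and 19.4 and 0.00966 CPM in the knockout. Vax2 and its neighbour Vax2os had superior minus inferior differences of -6.02 and -4.17 in the knockout, beside -3.50 and -2.33 in 2m controls. Kpna2, an importin, differed by 3.12 in the knockout and 1.54 in 2m controls. The adhesion gene Tenm3 had 31.1 CPM in inferior and 0.239 CPM in superior knockout cones, and 20.3 and 5.67 CPM in 2m controls. The knockout has 1 group per zone.

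Some markers of other retinal cells are given as mean CPM or its sum, superior before inferior. Cabp5, a bipolar marker, was at 31.9 and 193 CPM in 2m controls and at 375 and 316 CPM in the knockout. Its superior minus inferior difference was -1.33 at P21, -1.82 at P60, -2.56 in 2m controls and 0.25 in the knockout. In the controls that is the direction of S opsin, and whether Cabp5 RNA came from bipolar cells was not tested. Lhx4, which is also known from cones, was at 18.3 and 0.861 CPM in 2m controls and at 24.5 and 14.8 CPM in the knockout. Amacrine markers (3 of 9) summed to 22.5 and 13.6 CPM in 2m controls and 55.5 and 19.3 CPM in the knockout, horizontal cell markers (3 of 7) to 89.5 and 114 CPM and 137 and 125 CPM, and ganglion cell markers (3 of 9) to 13.6 and 78.1 CPM and 38.5 and 5.52 CPM. The endothelial and blood list held 1 measured gene of 8 (Kdr), at 17.6 and 0.106 CPM in 2m controls and 6.52 and 0 CPM in the knockout. Pigment epithelium markers had 0 of 8 genes measured.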
